A study of Drosophila suzukii with 24 samples.

How the data were processed

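Whole adult Drosophila suzukii, 5 to 7 days old, were profiled by RNA sequencing in 24 samples that form 8 groups of 3, with 10 individuals in each replicate. The groups cross 2 populations, flies taken from the field and flies reared in the laboratory, with 4 conditions: untreated flies, and flies that lived through a dose of spinosad, malathion or zeta-cypermethrin set at the concentration lethal to 50% of those exposed. Per the labels, libraries were paired-end and stranded, made from messenger RNA. The labels give neither the sex of the flies nor a sequencing batch, and nothing in them says whether replicates came from separate cultures or exposures, so the p-values may cover technical spread alone.

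The files are 6 gene tables, 1 for each insecticide and population, each setting survivors against the untreated flies of the same population. TopHat2 2.0.13, Cufflinks 2.2.1, Cuffdiff and FastQC are named in the submitters' processing notes. The genome build and the annotation are not given in the sources used here. Each table lists 13584 gene models on 902 scaffolds. Expression is in FPKM (fragments scaled by transcript length and by the fragments mapped in the library), which the authors deposited as 1 value per group, per the file headers, with the 3 replicates pooled. The deposited log2 fold change is survivors over untreated flies, and it is infinite where either group is listed at 0. A test statistic, a score of the fold change over its modelled error, is deposited beside it. The deposited p-value has a lowest listed value of 5e-05, and the q-value is the authors' false discovery rate over the genes tested in that table. Values per replicate were not analysed here, so no standard deviation, paired fit, left-out replicate or regrouping of samples could be computed. The FPKM values give no counts, so the depth of each library is unknown and no counting interval was computed. Locus starts are counted from 0 in the tables and are printed counted from 1; with the build not given, positions hold only within the authors' own scaffolds.

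In 4 of the 6 tables, those for malathion and zeta-cypermethrin, the group columns carry generic names. They were read as untreated flies first, from the order in the names of the tables. This reading was checked on the values. Within a population the first columns of the malathion and zeta-cypermethrin tables were the same up to 1 factor (Pearson r = 1 across genes on the log2 scale; ratio 0.972 in the field and 0.975 in the lab), with 97.9% and 100% of genes within 0.01 of it on the log2 scale. They also followed the named control column of the spinosad table (r = 0.987 in the field and 0.986 in the lab) but were not identical to it, and the reason is not known. The 3 tables of a population therefore share their untreated libraries. Field and lab tables were normalised separately, so levels set side by side across tables are descriptions without a test.

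A gene was called at a deposited q of 0.05 or less, as the authors' tables mark it. The IDs start with DS10_ and the files do not pair them with gene names. None of the 13584 IDs (0 matches) occurred in the reference table used here, which holds 18239 genes of another assembly. The 22 gene lists fixed before the data were examined (detoxification enzymes, stress, cuticle, immune, reproductive and tissue genes) could therefore not be applied, and the enrichment tests set out for them, in either form, were not run. Under the rule fixed for that case, at most 2 IDs that rose and 2 that fell are named per comparison: the called genes with the largest log2 fold changes in each direction, with both groups above 0 and at least 1 FPKM in 1 of them.

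Overlaps of calls between field and lab were tested with one-sided Fisher's exact tests over genes tested in both tables, adjusted by Benjamini-Hochberg over 6 tests. Correlations of fold changes are across genes, which are not independent replicates, and carry no p-value. The difference of a fold change between field and lab was tested as a normal z, with each standard error taken as the log2 fold change over the deposited statistic, and adjusted by Benjamini-Hochberg within an insecticide. These errors are wide at the median: a normal z made from the deposited p-value was 1.73 to 1.74 times the statistic at the median in each table. For some of the largest field rises they are narrower than errors made from the p-value. Tested on simulated data with 200 changed genes, the difference test recovered 2%, 8% and 8% of changes of 1 on the log2 scale and 71%, 65% and 59% of changes of 3, for spinosad (9256 genes), malathion (9561 genes) and zeta-cypermethrin (9493 genes), with 2, 4 and 4 false calls. The simulated noise was drawn from the same errors that the test used, so these rates hold only if those errors are right. For overlaps between insecticides, which share untreated libraries, 100 simulations of unchanged groups with a shared control were drawn at the observed numbers of calls. The simulations gave the untreated and the treated group equal error in every gene. For simulated correlations and covariances the errors from the statistic were first divided by the median ratio above, 1.73 to 1.74.

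The comparison of higher calls by expression level, the distances between groups, the sets of genes silent in untreated flies and the tests of neighbouring genes were chosen after the data had been seen. The level is that of the untreated flies of the other population, so that it does not enter the fold change. Weak genes were tested less often than strong ones, so the shares of higher calls were taken over all gene models and tested with Fisher's exact tests, adjusted by Benjamini-Hochberg over 12 tests, 6 of them over tested genes alone. Distances are the median absolute deviation of the log2 FPKM ratio after centring, over the 8103 genes at 1 FPKM or more in all 8 groups. Alternatives covered a q of 0.01, a fold change minimum, an FPKM minimum of 1, recomputed q-values, recentred fold changes, genes listed at 0 left out, and pseudocounts of 1 and 0.1. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.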

Results

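Drosophila suzukii, the spotted wing drosophila, lays its eggs in ripening soft fruit and is controlled mainly with insecticides. The series asks which genes differ in flies that outlive an insecticide, and whether flies from the field and from laboratory rearing differ alike under insecticides of 3 classes. Spinosad, a fermentation product, acts on nicotinic acetylcholine receptors. Malathion, an organophosphate, inhibits acetylcholinesterase, and zeta-cypermethrin, a pyrethroid, acts on voltage-gated sodium channels. RNA of whole adults was sequenced in 24 samples, 3 for each of 8 groups: untreated, spinosad, malathion and zeta-cypermethrin flies of each population. The authors' deposited tables give 1 FPKM value per group, pooled over its 3 replicates, so the group values below carry no spread, and the error enters only through the authors' test. Depth per library is unknown, because the tables hold no counts.

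The number of genes called differed far more between the field and lab comparisons than between insecticides. The 3 comparisons of a population share their untreated libraries, so an untreated group that stood apart would raise all 3 counts together. Of 13584 gene models, between 2319 and 5161 passed the authors' test in the 3 field comparisons, against 286 to 582 in the 3 lab comparisons. In the field, genes called higher in survivors outnumbered those called lower under each insecticide, and their median change was the larger one; for zeta-cypermethrin the order was reversed among genes at 10 FPKM or more in untreated lab flies, with 1332 higher and 2065 lower. In at least 1 of the 6 comparisons 5929 genes were called, 19 genes were called higher in all 6, and 4 lower in all 6.

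**Figure D1:**
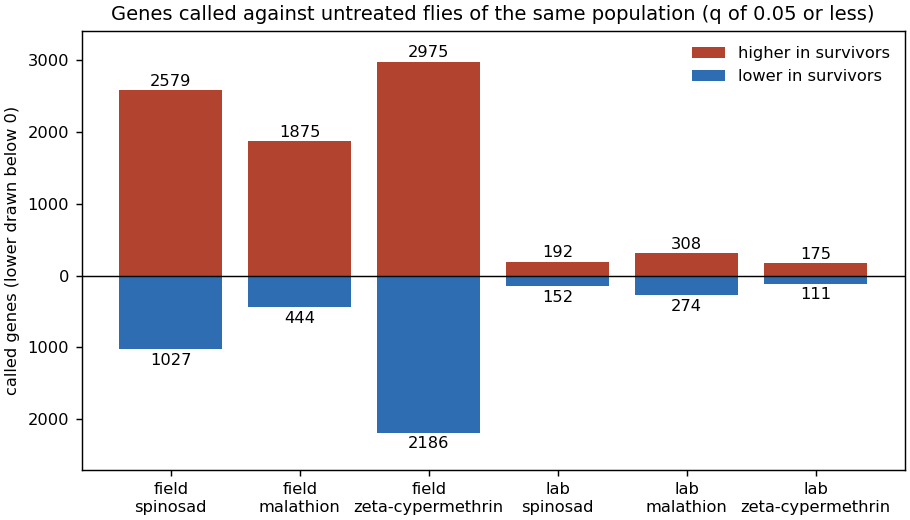
Number of genes called higher (above 0) and lower (below 0) in survivors than in untreated flies of the same population, at a deposited q of 0.05 or less, for each insecticide and population. The field bars reach 2579, 1875 and 2975 genes higher, and the lab bars 192, 308 and 175.

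The 8 groups were first set side by side on the 8103 genes at 1 FPKM or more in every group. Untreated field flies lay far from most other groups. Their distance to untreated lab flies was 0.423 on the log2 scale, to field spinosad survivors 0.419 and to field zeta-cypermethrin survivors 0.403, whereas field malathion survivors were closer, at 0.207. Among the other 7 groups the distances ran from 0.122 to 0.274, and the field survivors of spinosad, malathion and zeta-cypermethrin lay 0.212, 0.250 and 0.228 from untreated lab flies. The tables of both populations were normalised separately and no replicate spread is at hand, so these distances describe the groups and were not tested.

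**Figure D2:**
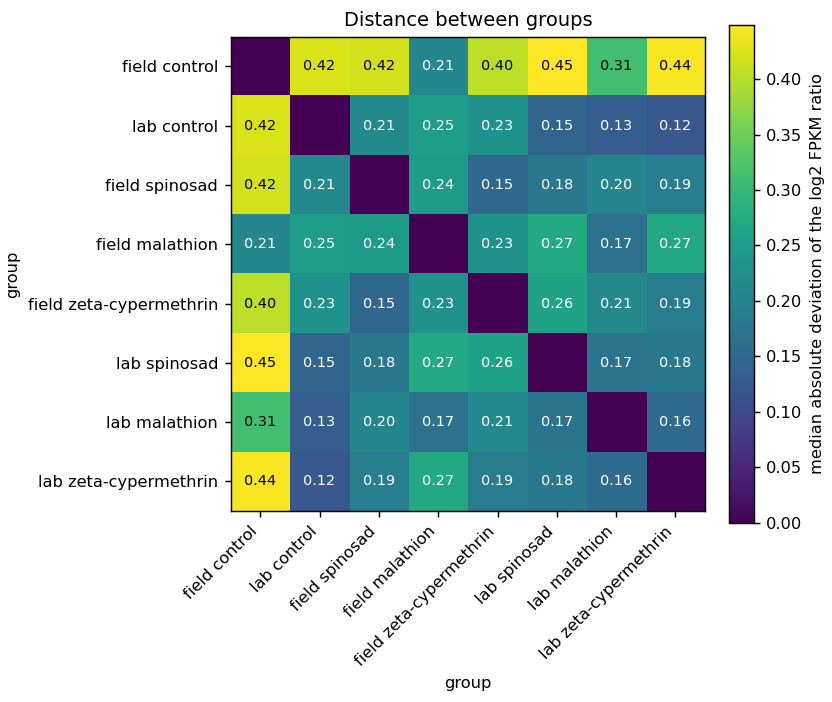
Distance between each pair of the 8 groups, as the median absolute deviation of the centred log2 FPKM ratio over 8103 genes; both axes list the groups and the colour scale gives the distance on the log2 scale. Untreated field flies show distances of 0.40 or more to every group except the malathion survivors of the field (0.21) and of the lab (0.31).

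Field flies that survived spinosad differed from untreated field flies in 3606 of 9973 tested genes. Of these, 2579 were higher, 2403 of them at least 2-fold, and 1027 were lower, 120 of them at least 2-fold. Higher calls made up 42.9% of the tested genes under 10 FPKM in untreated lab flies and 17.3% of those at 10 FPKM or more. Over all gene models, tested or not, these shares were 20.7% and 17.2%, a smaller gap that also passed (Fisher's exact test, two-sided, adjusted p = 2.5e-07; odds ratio 1.26). In 230 of the higher genes the untreated group was listed at 0. The largest finite rises in the authors' deposited table were those of DS10_00000320 (scaffold 1, 3894133 to 3899177), from 0.148 to 314 FPKM (log2 fold change 11.05, q = 0.0357), and of DS10_00012013 (scaffold 282, 130767 to 132666), from 0.198 to 366 FPKM (10.86, q = 0.0398). The largest falls in the authors' deposited table were those of DS10_00006562 (scaffold 8, 846242 to 847342), from 3.89 to 0.448 FPKM (−3.12, q = 0.0170), and of DS10_00013301 (scaffold 1662, 3 to 1568), from 5.44 to 0.851 FPKM (−2.68, q = 0.00210). The same untreated flies stand at 18.3 FPKM for DS10_00013301 in the authors' deposited table for malathion, so its level depends on the table. The median log2 fold change of the higher genes with both groups above 0 was 2.07, that of the lower genes −0.76. Most of the lower calls depended on the scaling. Genes at 50 FPKM or more in untreated lab flies had a median log2 fold change of −0.22, and with that median set to 0, a scaling chosen after seeing the data that leaves out genes listed at 0, the split was 2632 higher and 163 lower.

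Malathion survivors of the field population differed from untreated field flies in 2319 of 10531 tested genes, with 1875 higher and 444 lower. At least 2-fold differences numbered 1621 higher and 53 lower. Over all gene models 16.1% of those under 10 FPKM in untreated lab flies and 11.4% of the others were called higher (Fisher's exact test, two-sided, adjusted p = 3.8e-15; odds ratio 1.49), and 549 of the higher genes were listed at 0 in untreated flies. In the authors' deposited table DS10_00013464 (scaffold 4142, 374 to 2819) rose from 0.396 to 787 FPKM (log2 fold change 10.96, q = 5.1e-04) and DS10_00004610 (scaffold 3, 11580981 to 11583392) from 0.276 to 399.7 FPKM (10.50, q = 0.00630). The authors' deposited table has as its largest falls those of DS10_00012634 (scaffold 488, 75108 to 76805), from 4.03 to 0.241 FPKM (−4.06, q = 0.0227), and of DS10_00004166 (scaffold 3, 6515833 to 6528848), from 2.06 to 0.125 FPKM (−4.04, q = 0.0248). For DS10_00004166 the same untreated flies stand at 0.845 FPKM in the authors' deposited table for spinosad, so the size of its fall depends on the table. With the strongly expressed genes, whose median was −0.14, set to 0 in the same way, the split was 1525 higher and 75 lower.

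Zeta-cypermethrin survivors from the field differed most, in 5161 of 10694 tested genes. The 2975 higher genes had a median log2 fold change of 1.97 where both groups were above 0, and 2540 were at least 2-fold higher. The 2186 lower genes had a median of −0.60, and 81 were at least 2-fold lower. Of all gene models under 10 FPKM in untreated lab flies 23.9% were called higher, against 19.9% of the others (Fisher's exact test, two-sided, adjusted p = 2.2e-08; odds ratio 1.27), and 542 higher genes were listed at 0 in untreated flies. DS10_00013464 and DS10_00004610 again had the largest rises in the authors' deposited table, from 0.384 to 1207 FPKM (log2 fold change 11.62, q = 2.7e-04) and from 0.267 to 679 FPKM (11.31, q = 0.00270). The largest falls in the authors' deposited table belonged to DS10_00004253 (scaffold 3, 7637894 to 7638313), from 2.14 to 0.167 FPKM (−3.68, q = 0.0406), and again to DS10_00004166, from 1.99 to 0.164 FPKM (−3.61, q = 0.0282). None of the falls named for the 3 field comparisons (0) passed with errors taken from the deposited statistic, which are wider, although recentring on the median left their folds about as large, such as −3.06 for DS10_00006562 under spinosad. With strongly expressed genes, whose median was −0.17, set to 0 in the same way, the split was 2760 higher and 1058 lower.

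**Figure D3:**
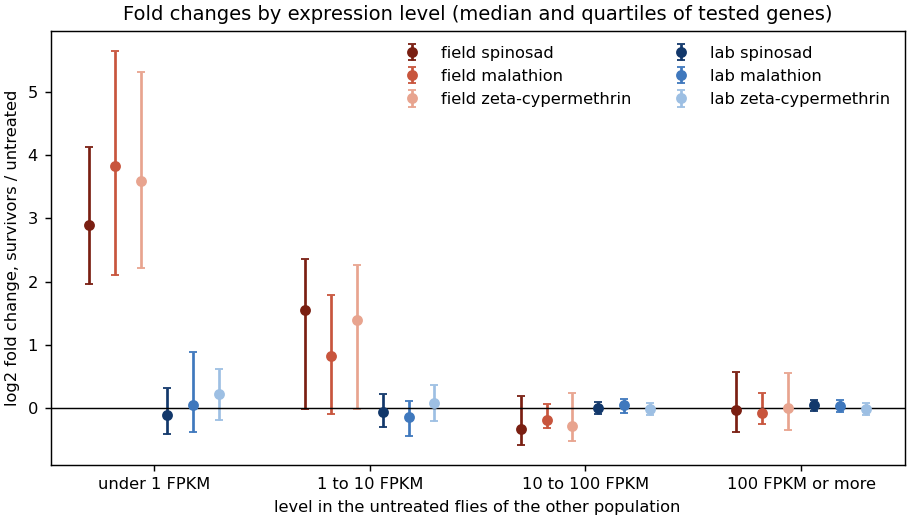
Median log2 fold change (survivors over untreated flies; points) with the first and last quartiles (bars) of tested genes with both groups above 0, by their FPKM in the untreated flies of the other population; weak genes that were not tested are left out. In the class under 1 FPKM the field medians are 2.90, 3.83 and 3.59 for spinosad, malathion and zeta-cypermethrin, and the lab medians −0.10, 0.05 and 0.23.

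In the lab population, spinosad survivors differed from untreated flies in 344 of 9487 tested genes, with 192 higher and 152 lower. The median log2 fold change was 1.12 for the higher genes and −0.89 for the lower ones. In the authors' deposited table DS10_00001389 (scaffold 1, 16036154 to 16037409) rose from 0.344 to 8.09 FPKM (log2 fold change 4.56, q = 0.00246) and DS10_00006586 (scaffold 8, 1018127 to 1018920) from 7.54 to 117 FPKM (3.95, q = 0.00246). DS10_00008471 (scaffold 40, 7341 to 8754) fell from 6.03 to 0.757 FPKM (−2.99, q = 0.00246) and DS10_00009027 (scaffold 62, 66702 to 71855) from 11.8 to 1.99 FPKM (−2.57, q = 0.00246) in the authors' deposited table. The fall of DS10_00009027 did not pass with errors taken from the deposited statistic. Higher calls made up 1.55% of gene models under 10 FPKM in untreated field flies and 1.24% of the others, a difference that did not pass the test (Fisher's exact test, two-sided, adjusted p = 0.14). Among tested genes alone the shares were 3.43% and 1.26% (Fisher's exact test, two-sided, adjusted p = 5.9e-12, odds ratio 2.79), with weak genes tested less often.

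Lab flies that survived malathion differed in 582 of 10329 tested genes, 308 higher and 274 lower. For 218 of the 308 higher genes the untreated lab flies were listed at 0, and without genes listed at 0 the split was 90 higher and 274 lower. Of gene models under 10 FPKM in untreated field flies 3.85% were called higher, against 0.372% of the others (Fisher's exact test, two-sided, adjusted p = 1.1e-49; odds ratio 10.7). In the authors' deposited table the largest finite rises were from 0.0268 to 1.47 FPKM for DS10_00009428 (scaffold 49, 38229 to 50052; log2 fold change 5.78, q = 0.0419) and from 0.0610 to 1.60 FPKM for DS10_00000361 (scaffold 1, 4192146 to 4197064; 4.71, q = 0.0484). With a pseudocount of 1 these log2 fold changes were 1.27 and 1.29. The falls of DS10_00006580 (scaffold 8, 978272 to 979054), from 19.2 to 0.791 FPKM (−4.60, q = 0.00191), and of DS10_00000033 (scaffold 1, 254096 to 298173), from 192 to 24.4 FPKM (−2.97, q = 0.0207), were the largest in the authors' deposited table. DS10_00000361 and DS10_00000033 did not pass with errors taken from the deposited statistic.

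Zeta-cypermethrin survivors of the lab population had the fewest calls, 286 of 9761 tested genes, with 175 higher and 111 lower. With a log2 fold change of at least 1 in either direction, lab spinosad survivors had fewer, 174 against 217. In the authors' deposited table DS10_00005509 (scaffold 6, 633915 to 635067) rose from 5.36 to 244 FPKM (log2 fold change 5.51, q = 0.00323) and DS10_00005807 (scaffold 6, 3705041 to 3707320) from 4.81 to 111 FPKM (4.53, q = 0.00323). DS10_00006580 fell under this insecticide as well, from 18.7 to 1.42 FPKM (−3.72, q = 0.00323) in the authors' deposited table. Genes called higher were 1.59% of gene models under 10 FPKM in untreated field flies and 0.922% of those at 10 FPKM or more (Fisher's exact test, two-sided, adjusted p = 6.0e-04; odds ratio 1.74).

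Field and lab survivors of the same insecticide shared more of their higher genes than independent lists would. For spinosad 139 genes were higher in both populations, where independent lists would share 45.9; for malathion the numbers were 233 and 48.02, and for zeta-cypermethrin 151 and 42.8 (one-sided Fisher's exact tests, adjusted p = 4.9e-47, 6.6e-128 and 2.5e-69). Shared lower genes exceeded independent lists only for malathion, 33 against 12.01 (Fisher's exact test, adjusted p = 1.7e-07); spinosad had 16 against 16.3 (adjusted p = 0.68) and zeta-cypermethrin 18 against 22.7 (adjusted p = 0.90). Of the 233 genes shared under malathion, 176 were under 0.1 FPKM in both untreated groups; among genes at 1 FPKM or more in both, a limit set after seeing the data, 34 were shared against 6.66 for independent lists (Fisher's exact test, adjusted p = 5.4e-18). The same limit left 116 shared higher genes for spinosad and 118 for zeta-cypermethrin. Fisher's exact tests treat genes as independent. Among tested genes, higher calls were more frequent in weak genes in every comparison, so the numbers for independent lists may be too low. Field and lab lists of unlike insecticides were not set against each other, so this sharing is not shown to belong to the insecticide. DS10_00005807, the second largest rise in lab zeta-cypermethrin survivors, was called higher in all 6 comparisons, with log2 fold changes from 3.44 to 4.53 in the authors' deposited tables. Genes called in opposite directions in the 2 populations numbered 81 for spinosad, 57 for malathion and 17 for zeta-cypermethrin. No number for independent lists was computed for opposite calls, so these counts alone do not show that the populations diverged.

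Across genes, the field and lab fold changes went together for zeta-cypermethrin (Pearson r = 0.469, Spearman rho = 0.437, 9493 genes). For spinosad r was 0.111 and rho −0.034 over 9256 genes, and for malathion r was 0.542 and rho −0.093 over 9561 genes, so that the measures differed in sign for these insecticides. With a pseudocount of 1 the malathion r was 0.316. The same sign in field and lab was found for 45.3%, 38.9% and 66.8% of genes under spinosad, malathion and zeta-cypermethrin.

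**Figure D4:**
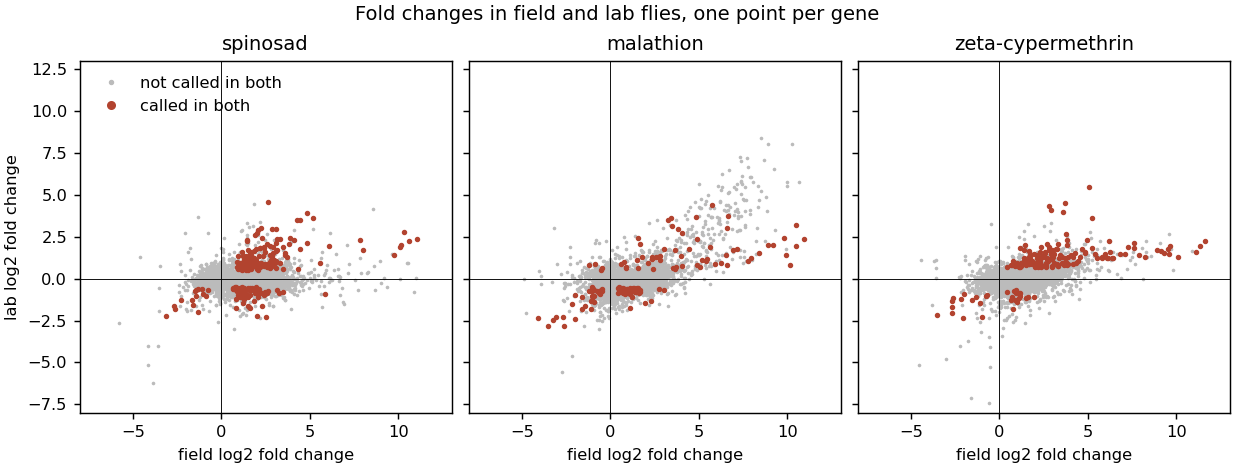
Log2 fold change in field flies (x axis) against lab flies (y axis) for each insecticide, 1 point per gene tested in both tables with all groups above 0; red points were called in both populations. Red points lie mostly to the right of 0, and for spinosad and malathion they fall both above and below 0 in the lab.

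A test of the difference itself found 563 genes whose spinosad fold change differed between field and lab, 294 for malathion and 349 for zeta-cypermethrin (normal z from the authors' statistics, adjusted p of 0.05 or less). The field fold change was the higher one in 563, 291 and 348 of them, with median differences of 2.74, 2.11 and 2.27 on the log2 scale. For spinosad, 442 of the 563 had a fold change above 0 in the field and below 0 in the lab. Below 0 counts any negative lab value, called or not. Only 152 genes in all were called lower in lab spinosad survivors, so most of these lab values were not called. The errors behind this test are wider at the median than those behind the deposited p-values, though narrower for some of the largest field rises. With errors taken from the p-values, a choice made after seeing the data, 2245, 1272 and 1159 genes differed. The field fold change was the lower one in 355, 233 and 150 of them.

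Within the field population 1433 genes were called higher under all 3 insecticides, of 2932 called higher under any, among 9684 genes tested in the 3 tables. Of 2301 genes called lower under any, 309 were lower under all 3; the malathion list of 440 lower genes is the shortest and limits that number. DS10_00013464 was among the shared higher genes, at 1556-fold, 1988-fold and 3141-fold under spinosad, malathion and zeta-cypermethrin by the authors' deposited tables. Its untreated values were low (0.405, 0.396 and 0.384 FPKM), so these folds are uncertain. With a pseudocount of 1 its log2 fold change was 9.14 in place of 10.96 under malathion and 9.77 in place of 11.62 under zeta-cypermethrin. Independent lists would share 104 and 10.5 genes, and unchanged groups that share a control gave at most 596 and 160 in 100 simulations. Fold changes of pairs of insecticides correlated across genes at r = 0.906 (spinosad and malathion), 0.952 (spinosad and zeta-cypermethrin) and 0.962 (malathion and zeta-cypermethrin). Over genes at 1 FPKM or more in both untreated groups r was 0.869, 0.937 and 0.922, against 0.445, 0.445 and 0.497 simulated for a shared control with no change. The covariances of these pairs over the same genes were 0.777, 1.10 and 0.792, against 0.0872, 0.0860 and 0.0781 simulated. The untreated libraries could not be split, so part of the excess may come from them, and with strongly expressed genes set to 0 the genes lower under all 3 numbered 27 in place of 309, while those higher numbered 1422.

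In the lab population 29 of 313 genes higher under any insecticide were higher under all 3, and 26 of 394 lower genes were lower under all 3, among 9388 tested in the 3 tables. DS10_00006586 was one of the 29, at 15.5-fold, 9.06-fold and 15.7-fold for spinosad, malathion and zeta-cypermethrin in the authors' deposited tables, and DS10_00008471 one of the 26, at 7.96-fold, 5.44-fold and 4.14-fold lower. Independent lists would share 0.028 and 0.052 genes, and simulated unchanged groups with a shared control gave at most 11 and 17. Pairs of insecticides correlated at r = 0.472, 0.530 and 0.583, in the order used for the field. Over genes expressed in both untreated groups r was 0.378, 0.463 and 0.537, against 0.461, 0.456 and 0.478 simulated for a shared control with no change, so that the spinosad and malathion pair lay below its simulated value. The covariances over these genes were 0.0568, 0.0741 and 0.0835, against 0.0482, 0.0517 and 0.0576 simulated. The simulated errors were reduced to the scale of the p-values, and undivided errors from the statistic would give larger simulated covariances. This small excess thus depends on that choice, and part of these overlaps too may come from the shared libraries.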

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

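The distances between groups, the split of the shared-control test by direction and the use of the difference test against an equal response were chosen only after the results had been seen, and the recentring on strong genes was added after seeing the data; the difference test itself was fixed before the data were examined.

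The fold change of survivors over untreated flies differed between field and lab in 563 genes for spinosad, 294 for malathion and 349 for zeta-cypermethrin, by a z test of the difference made from the authors' statistics. Named genes were among them. Those given here were chosen for the largest field rises, which by itself favours a field fold change above that of the lab, so they are examples and no added support. In log2 fold change of field minus lab, with z from the authors' statistics, DS10_00000320 differed by 8.69 under spinosad (adjusted p = 4.8e-05) and DS10_00012013 by 11.67 (adjusted p = 4.5e-10). DS10_00012013 went from 0.198 to 366 FPKM in the field, while in the lab it stood at 34.9 FPKM in untreated flies and 19.8 FPKM in spinosad survivors, by the authors' deposited tables. By the same z from the authors' statistics, DS10_00004610 differed by 8.53 under malathion (adjusted p = 8.7e-06) and by 9.38 under zeta-cypermethrin (adjusted p = 7.5e-07). Also from the authors' statistics, DS10_00013464 differed by 8.61 under malathion (adjusted p = 3.2e-10) and by 9.33 under zeta-cypermethrin (adjusted p = 2.1e-10). The deposited Cuffdiff p of the field rise under spinosad was only 0.01125 for DS10_00000320 and 0.01315 for DS10_00012013. For DS10_00004610 it was 0.0008 under malathion and 0.0007 under zeta-cypermethrin. Errors from the statistic were narrower than errors from those p-values, so the adjusted p-values above overstate the certainty. For DS10_00013464 the deposited p was 5e-05, the lowest listed, so this could not be checked. DS10_00004610 and DS10_00013464 were called higher in the lab as well for malathion and zeta-cypermethrin, at log2 fold changes between 1.94 and 2.35 in the authors' deposited tables.

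Between 2319 and 5161 genes differed in the field, and many under all 3 insecticides, a pattern that could come from the survivors or from the untreated field flies they were set against. Field spinosad and zeta-cypermethrin survivors lay closer to untreated lab flies (0.212 and 0.228) than to untreated field flies (0.419 and 0.403). An untreated field group that is out of place would give this. Malathion survivors lay 0.250 from the lab and 0.207 from the field group. The Pearson r of their log2 levels leaned the other way, 0.941 with untreated lab flies and 0.934 with untreated field flies. For malathion, an untreated field group out of place thus cannot be told apart from a response. At 1 error model recentring left at least 1.01 times as many calls in every field table. That count could hardly fall, since 879 of 890, 497 of 520 and 1108 of 1340 calls were higher beforehand. Recentring then raised the fold changes. With errors from the p-values, lower calls numbered 163, 75 and 1058 in place of 1027, 444 and 2186, so scaling stays open for them. Scaling alone is argued against for the higher calls, since the strongly expressed genes had medians below 0 (−0.22, −0.14 and −0.17). A control shared by 3 unchanged groups gave at most 0.416 of the genes higher and 0.518 of those lower under all 3. That simulation gave untreated and treated groups equal error, so it cannot exclude an untreated field group of larger error. Recentring with errors from the p-values left 27 shared lower genes of 309. Whether the response was the same in both populations could not be decided. The fold change differed between them in 563, 294 and 349 genes, and for zeta-cypermethrin fold changes went together across genes (rho = 0.437). The field fold change was the higher one in 563, 291 and 348 of those genes. Field fold changes are set against untreated field flies, so an untreated field group out of place would give such differences by itself. Open are a difference in how the untreated field flies were collected, kept or sequenced, which the labels do not describe, and a response to exposure or a selection of survivors that is particular to field flies, which was not tested.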

How the results depend on the processing

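Tests that counted calls from the statistic as a z without recentring, took errors from the p-values, recentred on strongly expressed genes or kept only genes expressed in untreated flies were chosen after the results had been seen; the other alternatives were fixed before the data were examined. No paired analysis was possible because the tables hold 1 pooled value per group; for the same reason no replicate could be left out and no other split of the samples could be made, so chance differences between groups of 3 were not tested beyond the authors' own test. The gene list tests were not run in either form, since no list could be applied. FPKM without counts leaves the depth behind weak genes unknown. Of 172 alternative values for 49 results, 97 kept their size or call, 65 moved and 10 lost the threshold; no single fold change or correlation changed sign (0 values). Of 48 values for fold changes chosen by the naming rule, 15 moved with a pseudocount of 1, which shrank weak genes most: DS10_00009428 from 5.78 to 1.27 and DS10_00000361 from 4.71 to 1.29 in lab malathion, by the authors' deposited table. Another 10 lost the threshold when recentred with errors from the statistic, with folds about as large. None of the 10 passed with those errors before recentring. They were all falls named for the field, DS10_00000361 and DS10_00000033 in lab malathion, DS10_00009027 in lab spinosad and DS10_00008629 in lab zeta-cypermethrin.

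At a q of 0.01, calls fell to 2070 (field spinosad), 1453 (field malathion), 382 (lab malathion) and 178 (lab zeta-cypermethrin); genes lower in both populations to 6 (spinosad), 18 (malathion) and 10 (zeta-cypermethrin), and genes higher in both to 73 for zeta-cypermethrin. Genes differing between field and lab fell to 323, 158 and 188 for spinosad, malathion and zeta-cypermethrin at an adjusted p of 0.01, and genes under all 3 insecticides to 926 higher and 48 lower in the field and 14 and 16 in the lab. A minimum log2 fold change of 1 left 2621 calls in field zeta-cypermethrin and 174 in lab spinosad. In the order field then lab, each as spinosad, malathion and zeta-cypermethrin, the statistic read as a z gave 890, 520, 1340, 66, 55 and 29 calls; recentred on the median 976, 571, 1355, 66, 55 and 29; and recentred on genes of 50 FPKM or more 1270, 637, 1353, 67, 55 and 30. These counts leave out genes listed at 0 and use a statistic smaller at the median than the z of the p-value, so more than 1 choice changed. With errors from the p-values, recentring on strong genes left 324 calls in lab malathion and 27 genes lower under all 3 in the field. The field splits under it were 94.2%, 95.3% and 72.3% higher, against 71.5%, 80.9% and 57.6% as deposited. Leaving out genes listed at 0 gave 364 calls in lab malathion, and called genes at 1 FPKM or more in the other population's control 316. The slight majority of higher calls in lab malathion (52.9%) depended on the setting: it was 58.4% at a q of 0.01 and 72.3% with a log2 fold change of 1 or more, but 48.7% with 1 FPKM or more in a group, 38.2% recentred on the median, 24.7% without genes listed at 0 and 17.4% over genes expressed in the other control. Genes expressed in both controls left 19 higher under all 3 in the lab and 34 higher in both populations under malathion. Errors from the p-values raised the field-lab differences to 2245, 1272 and 1159. The malathion r was 0.316 with a pseudocount of 1, 0.465 with 0.1 and 0.509 over genes at 1 FPKM or more, with rho −0.118 and −0.127 under the first and last; the zeta-cypermethrin r was 0.503 with a pseudocount of 1. The cause of the moves in r was not tested.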

Other observations

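The tests on control contrasts, on genes silent in untreated flies and on ratios between groups were chosen only after the pattern had been seen; the overlap test of silent genes and the neighbour test were set before their results.

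Most genes that were far higher in untreated lab flies than in untreated field flies were also called higher in field survivors. At 10 FPKM or more in untreated lab flies and over 4 times the untreated field level there were 342 genes, and 5 genes the opposite way. Their median was 4.32 FPKM in untreated field flies and 24.3 FPKM in untreated lab flies, and 22.2, 13.9 and 19.6 FPKM in field survivors of spinosad, malathion and zeta-cypermethrin. Of the 342, 283, 199 and 266 were called higher in these survivors. In lab survivors 11, 19 and 33 of them were called higher and 34, 85 and 36 lower. The levels come from tables normalised separately, and the set was chosen on a low untreated field value, which favours higher calls in the field, and a high untreated lab value, which favours lower calls in the lab, so these counts are a description.

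A set of 2530 genes was under 0.1 FPKM in both untreated groups, and many of them appeared in survivors of some groups. At 1 FPKM or more were 240 in field spinosad, 713 in field malathion, 678 in field zeta-cypermethrin and 278 in lab malathion survivors, against 12 in lab spinosad and 10 in lab zeta-cypermethrin survivors. Called higher were 188, 495, 475 and 217 of them in the first 4 groups. For 185, 493, 472 and 213 of these the untreated group was listed at 0, so nearly all of these calls rest on infinite fold changes. Genes chosen for low untreated values could hardly be called lower, and 0 were. The 713 genes spanned a median of 1014 bp, compared with 2890 bp for genes at 1 FPKM or more in both untreated groups.

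Noise near the floor is argued against as the origin of this set, since 598 genes reached 1 FPKM under both malathion and zeta-cypermethrin in the field (odds ratio 113, Fisher's exact test, two-sided, p at or below 1e-300). A candidate explanation is 1 source of RNA present in different amounts in these pools, and its genes would then keep 1 ratio between groups. The spread of the log2 ratio was taken only over genes of the set with a mean of 1 FPKM or more in the groups compared. Over 699 such genes it was 0.396 between field malathion and field zeta-cypermethrin, under the central 95% of matched expressed genes (0.422 to 0.506). Between field and lab malathion it was 0.396 over 529 genes (0.441 to 0.552), where the field level was 3.45 times the lab level. The rest of the 2530 genes did not enter these spreads. A set of genes switched on together in survivors would keep a like ratio, so co-regulation stays open, as do RNA of a different sex, tissue or organism in some pools. The labels give no sex and the IDs no names, so no markers could be tested.

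Called genes lay next to each other along the scaffolds more often than at random. Neighbouring pairs called in the same direction numbered 794, 422 and 1417 in the field tables and 21, 59 and 15 in the lab tables (spinosad, malathion, zeta-cypermethrin). Random placements that kept each gene's level class gave means of 593, 279, 1092, 4.89, 13.5 and 3.26, and the lowest ratio of observed to random was 1.30 (permutation test, one-sided, p = 0.001 in each table, the smallest that 1000 placements can give). Among the longest runs, 5 genes on scaffold 10 (456385 to 475526) were higher in lab spinosad survivors and 4 in part of the same stretch (456385 to 467498) in lab malathion survivors, and 3 genes on scaffold 1 (19565702 to 19573343) were lower in lab malathion and in lab zeta-cypermethrin survivors. The lab comparisons share their untreated libraries, so a stretch that stood apart in those libraries would recur in the same way. Gene clusters of related function and reads shared between neighbouring copies of a gene would both give such runs, and without sequences or names neither was tested.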
